A study of Mus musculus with 78 samples.

How the data were processed

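Liver mRNA of LDLr-/-.Leiden mice on a C57BL/6 background was measured in 78 libraries, per the labels: chow at weeks 0, 6, 12, 18 and 24 (6 libraries each) and HFD at weeks 6, 12, 18 and 24 (12 libraries each). Tissues were flash frozen and strand-specific mRNA libraries were sequenced on the Illumina platform, per the labels' protocols. Per the submitters' processing notes, TopHat2 2.0.14, Bowtie2 2.1.0 and SAMtools 0.1.18 were used with genome build GRCm38, and HTSeq 0.6.1p1 was used for counting. The annotation release, the HTSeq mode and the strand setting were not given in the sources used here.

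The deposited files hold raw HTSeq counts per Ensembl gene, with no normalization by the authors, as whole numbers for 47069 genes and 5 tally lines in each file. The tally lines stayed out of library sizes and tests. Over the 78 libraries, reads in no gene made up 5.74% of the tally on average, ambiguous reads 1.47% and alignments that were not unique 35.1%, and mitochondrial genes took 5.56% of gene counts. Gene symbols and coordinates came from the GENCODE M21 annotation of GRCm38, in which 46488 of the gene identifiers (98.8%) were found; 581 were not and kept their identifier. Counts for each gene cover the whole gene. The depth of 5502872 to 14575152 gene counts per library limits what can be seen for genes with few reads.

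Samples were grouped by diet and week from the sample titles. File names also carry 1 of 5 sequencing flow cells, which were not balanced: the week 6 chow libraries came from 2 flow cells (4 and 2 libraries) and the week 6 HFD libraries from all 5. Within groups no pair of libraries looked like the same sample counted again, which was checked over the 339 pairs (lowest chi-square per degree of freedom 4.58, median 16.2).

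Genes were tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr by group, estimateDisp, a robust quasi-likelihood fit with a mean for each of the 9 groups, and the quasi-likelihood F-test. Of the genes, 13457 passed the filter, and the common biological coefficient of variation was 0.223. P-values were adjusted by the Benjamini-Hochberg method over these genes, and a gene was called past an adjusted p of 0.05; tests were two-sided. The contrasts were HFD against chow at each of 4 weeks, the diet by week interaction (3 degrees of freedom), the change of the diet effect between weeks 6 and 24 and between neighbouring weeks, chow at week 24 against week 0, and any change over the 5 chow groups (4 degrees of freedom). CPM used TMM-scaled library sizes for groups of genes reported by diet and week, and plain library sizes for the profiles of single libraries; log2 CPM used a prior count of 2. Fold changes against a group without counts were treated as bounds at a floor of 3 counts over the group. Floors cover counting error only.

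Before the data were examined, 36 lists with 591 genes were fixed: extracellular matrix structure, matrix remodelling, stellate cell, myofibroblast, TGF-beta response, Kupffer cell, lipid-associated macrophage, monocyte and macrophage, MHC class II, neutrophil, T and NK cell, B and plasma cell, cytokines and chemokines, cholangiocyte, sinusoidal endothelial, hepatocyte, cholesterol synthesis, fatty acid synthesis, lipid droplet, PPAR-alpha, bile acid, xenobiotic, NRF2, acute phase, stress response, proliferation, interferon, circadian clock, glucose and insulin, male-biased, female-biased, pancreas, adipocyte, erythroid, skeletal muscle and mesothelial. Of these, 35 had a tested member and 34 had the 3 members needed for a set test. Sets were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists, and again with the correlation estimated for each list. The comparisons and the rule for named genes were fixed at the same point. Per comparison the rule allows the 5 largest rises and 5 largest falls with a mean of at least 3 log2 CPM, a proper symbol and all 12 HFD libraries on 1 side of the chow mean, the 3 members of each list with the smallest p and the called member against the list's majority, and a panel of 29 genes led by Ldlr. Other members named in counts of 5 or fewer, and the genes of the profiles of single libraries, were chosen after their values were seen.

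The alternatives tried were DESeq2 size factors, the DESeq2 1.42.0 test, no filter on low counts, a filter of at least 1 CPM in 6 libraries, flow cell as a term, fits on the libraries of the comparison alone, leaving out each library of a week in turn, and an estimated correlation in camera. Added after the data were seen were fits without chow library 466 of week 0, fits with a clock score as a term, and fits with flow cell without that library. Each gene count was also compared with that of 100 splits of the same libraries into groups of the same sizes, for the chow counts also without library 466. Tests were tried on 13293 simulated genes for the week 24 diet effect. Of 100 changed 1.5-fold, 68 were called, with a median log2 size of 0.59, and of 100 changed 2-fold, 84. Of 13093 unchanged genes, 13 were called. With 13303 genes the set test ranked a list lowered 1.5-fold in place 1 (adjusted p = 5.36e-23), with 0 of 33 other lists past. Splits of week 24 libraries gave a median of 13, so false list calls are not bounded. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No library was left out of the fits reported first.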

Results

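Liver mRNA was sequenced from LDLr-/-.Leiden mice, a C57BL/6 line deficient in the LDL receptor, kept on chow or on a high-fat diet (HFD). The study asked which expression changes mark the onset of fibrosis in non-alcoholic steatohepatitis. There were 78 strand-specific libraries: 5 chow groups of 6 libraries at weeks 0, 6, 12, 18 and 24, and 4 HFD groups of 12 libraries at weeks 6, 12, 18 and 24. Each library carried its own number, and the labels do not state in words that each number is a separate mouse. Counts assigned to genes ranged from 5502872 to 14575152 per library, with a median of 8991616; the mean was 8558882 on chow and 9737058 on HFD. The main question was how the liver on HFD differed from the liver on chow of the same week. In what follows, fold changes are HFD over chow, errors beside log2 fold changes are standard errors (SE), levels are CPM, counts scaled by library size, as mean ± SD over 12 HFD and 6 chow libraries, and p-values are adjusted over 13457 tested genes.

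Ldlr (chromosome 9, 21723483 to 21749919, GRCm38), the gene the line is deficient in, was counted in every group. Its mean level on chow was 341 ± 64.7 CPM at week 6, 358.4 ± 35.8 at week 12, 342.2 ± 21.4 at week 18 and 405.3 ± 64.8 at week 24. On HFD it was 237.8 ± 42.5, 277.9 ± 46.1, 260.2 ± 35.8 and 262.5 ± 28.3 CPM at the same weeks. A count over the whole gene checks nothing about the disrupted allele. The log2 fold change was -0.52, -0.37, -0.40 and -0.63, with adjusted p = 0.0638, 0.179, 0.086 and 0.00559, so the fall passed the test at week 24. At week 0 the level was 450.4 ± 47.7 CPM over 5 chow libraries and 24.47 CPM in the sixth, library 466. Without library 466, Ldlr passed at weeks 6, 12 and 18 as well (adjusted p = 7.37e-05, 0.00297 and 0.0006), and at week 6 it also passed without HFD library 499 (adjusted p = 0.0459).

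Library 466 of the week 0 chow group stood apart from the other 77 libraries. Its albumin transcript Alb measured 31.3 CPM, against 77830 ± 7170 CPM in the other 5 week 0 livers. The T-cell recombinase gene Rag1 stood at 2556 CPM, the T-cell coreceptor gene Cd8a at 856.2, the brown-fat uncoupling protein gene Ucp1 at 2357 and the airway gene Bpifa1 at 1116, each above the highest of the other 77 libraries. The library was kept in the fits as the design set out, and counts of genes are given with it and without it.

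The first principal component, computed without library 466, held 41.3% of the variance. Chow groups lay between a mean of -35.7 at week 24 and -32.2 at week 6. HFD groups lay at -8.83 at week 6, 11.8 at week 12, 41 at week 18 and 38.2 at week 24. At week 6, 4 of the 12 HFD libraries (506, 503, 496 and 500) lay within the chow range of -47.9 to -15.6, and the HFD groups of weeks 18 and 24 overlapped.

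**Figure D1:**
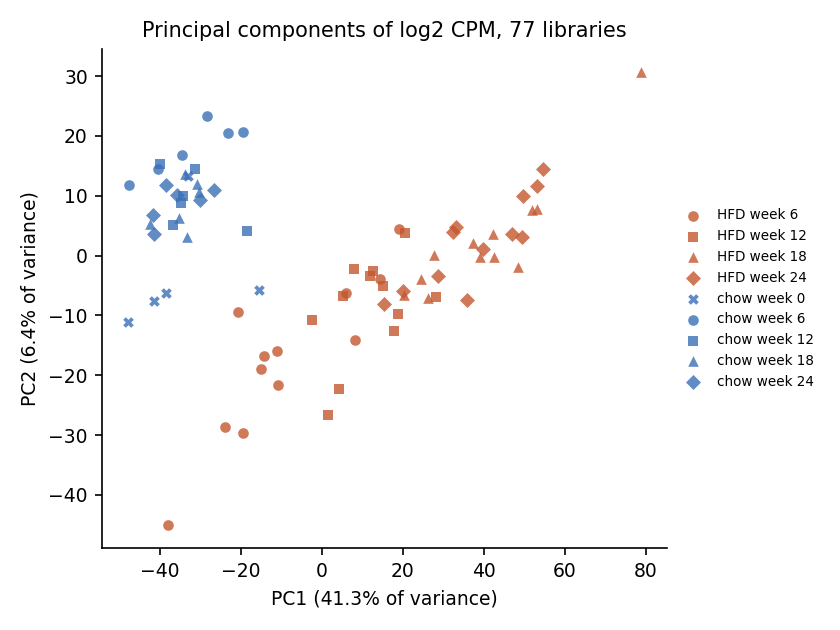
First against second principal component of log2 CPM for 77 libraries, with the percent of variance on each axis; each point is a library, coloured by diet and week. The HFD groups lay at mean PC1 values of -8.83, 11.8, 41 and 38.2 at weeks 6, 12, 18 and 24.

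At week 6 the liver on HFD had less of nearly every cholesterol synthesis transcript, a shifted set of circadian clock transcripts and more of several lipid uptake and lipid droplet transcripts. Sqle (chromosome 15, 59315077 to 59331192), which encodes squalene epoxidase of the sterol pathway, was 3.97-fold lower (log2 -1.99, SE 0.42, adjusted p = 0.000442). Cd36 (chromosome 5, 17781690 to 17888801), a fatty acid uptake receptor, was 2.31-fold higher (log2 1.21, SE 0.20, adjusted p = 5.96e-06), at 287.5 ± 80.5 against 124.4 ± 35.1 CPM. The fibrillar collagens Col1a2 and Col3a1 were 2.29-fold and 2.11-fold higher (adjusted p = 0.0168 and 0.0167). In total 1557 genes (11.6% of those tested) passed, 690 higher and 867 lower on HFD (176 and 192 by at least 2-fold). Without library 466, 2489 genes passed, and 1556 of the 1557 were among them.

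Of the 24 cholesterol synthesis genes, 23 fell and 1 did not pass (24 fell when adjusted over the list alone). The list was lower as a set, with adjusted p = 7.22e-36 in the camera test and adjusted p = 0.0479 with an estimated correlation. Srebf2, the transcription factor that drives the pathway, was 1.62-fold lower (adjusted p = 1.29e-06). The mevalonate pathway kinases Pmvk and Mvk were 3.17-fold and 2.48-fold lower (adjusted p = 1.47e-06 and 2.63e-06), below the chow mean in all 12 HFD livers.

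Of the 18 circadian clock genes, 10 rose, 6 fell and 2 did not pass, with the same counts when adjusted over the list alone. The clock output factor Dbp (chromosome 7, 45705088 to 45710203) was 41.4-fold higher (log2 5.37, SE 0.91, adjusted p = 1.28e-05), at 57.4 ± 34.8 against 1.41 ± 0.45 CPM. Per3, a repressor of the clock loop, was 7.11-fold higher. The activators Arntl and Npas2 were 4-fold and 8-fold lower, and the repressor Cry1 was 2.88-fold lower (adjusted p = 7.81e-06, 5.06e-07 and 1.29e-06). The list passed in the upward direction (camera adjusted p = 0.021, and adjusted p = 0.454 with an estimated correlation). A clock score, the mean log2 CPM of 6 evening-phase genes less that of 4 morning-phase genes, was -1.93 ± 0.29 on chow and 2.11 ± 0.90 on HFD, a difference of 4.04 (SE 0.28, exact permutation p = 5.39e-05, two-sided).

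Rgs16 (chromosome 1, 153740349 to 153745468), a regulator of G-protein signalling, rose most of the genes counted in both groups, 124-fold (log2 6.95, SE 0.87, adjusted p = 1.34e-08); without chow library 577 its log2 change was 7.65. Cyp2b9, a female-biased cytochrome P450 in mouse liver, was 58.5-fold higher, and its log2 change moved from 5.87 to 7.05 without chow library 477. The adipsin gene Cfd was 13.5-fold higher (log2 3.76, SE 0.84, adjusted p = 0.00109), and 4.36 on the log2 scale with flow cell as a term. Elovl3, a male-biased fatty acid elongase, was 6.25-fold lower, and Csad and Acmsd, enzymes of taurine synthesis and of tryptophan breakdown, were 5.17-fold and 5.1-fold lower (adjusted p = 2.31e-13 and 1.06e-08). The immediate early gene Egr1 was 8.22-fold lower (log2 -3.04, adjusted p = 1.45e-05), but without chow library 577, where it reached 806.8 CPM, the log2 change was -0.54 with adjusted p = 0.552.

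In the lipid droplet and lipid uptake list, 5 of 18 genes rose and 13 did not pass (5 rose when adjusted over the list alone; camera adjusted p = 6.21e-05, upward, and adjusted p = 0.105 with an estimated correlation). The 5 were Cd36, Plin3, Vldlr, the perilipin gene Plin4, 6.3-fold higher, and the fatty acid binding protein gene Fabp2, 2.53-fold higher. Among the 26 PPAR-alpha targets and fatty acid oxidation genes, 6 rose, 1 (Pdk4) fell and 19 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.00104, upward, and adjusted p = 0.454 with an estimated correlation). They included the receptor gene Ppara (1.82-fold higher), the pantetheinase gene Vnn1 (3.61-fold higher) and Fgf21, which encodes a fasting-induced hepatokine (6.3-fold higher, 4.36 ± 2.24 against 0.68 ± 0.40 CPM).

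In the extracellular matrix list 3 of 37 genes rose, Col1a2, Col3a1 and Col16a1, and 34 did not pass (3 rose when adjusted over the list alone; camera adjusted p = 0.00173, upward, and adjusted p = 0.84 with an estimated correlation). Col3a1 did not pass without chow library 476 (adjusted p = 0.0531), nor did Col16a1 without chow library 477 (adjusted p = 0.0537). Col1a1 was 2.33-fold higher but did not pass (adjusted p = 0.0596); it passed without library 466 (adjusted p = 0.0349), and without HFD library 505 or 506 (adjusted p = 0.0456 and 0.0446). Of 25 matrix remodelling genes, Timp1, Adamts2 and Mmp12 rose, Loxl4 fell and 21 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.00905, upward, and adjusted p = 0.737 with an estimated correlation). Mmp12, which encodes macrophage elastase, was 9.66-fold higher (log2 3.27, and 4.03 without chow library 575), and Loxl4, a collagen crosslinking oxidase, was 7.01-fold lower.

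Of the 14 lipid-associated macrophage markers, 6 rose, 1 fell and 7 did not pass (7 rose and 1 fell when adjusted over the list alone; camera adjusted p = 0.00508, upward, and adjusted p = 0.603 with an estimated correlation). The lipid receptor gene Trem2 was 3.39-fold higher (adjusted p = 0.0172), the glycoprotein gene Gpnmb 11.1-fold, the galectin gene Lgals3 2.07-fold and the integrin gene Itgax 3-fold, while the fatty acid binding protein gene Fabp5 was 4.64-fold lower. Of 18 cytokines and chemokines, 5 rose, 1 (Il1b) fell and 12 did not pass (7 rose and 1 fell when adjusted over the list alone; camera adjusted p = 0.00337, upward, and adjusted p = 0.603 with an estimated correlation). The 5 were Ccl4, Ccl6, Il1rn, the interleukin 1 receptor antagonist gene (2.67-fold), Cxcl10 (2.49-fold) and the monocyte chemoattractant gene Ccl2 (3.42-fold). The monocyte receptor gene Ccr2 alone rose of the 18 monocyte and macrophage markers, and 1 rose when adjusted over the list alone (camera adjusted p = 0.0407, upward, and adjusted p = 0.953 with an estimated correlation). That list did not pass without library 466 (camera adjusted p = 0.0695).

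In the interferon response list Mx1, Ifi44, Gbp3, Usp18 and Ifit3 rose and 20 of 25 genes did not pass (6 rose when adjusted over the list alone; camera adjusted p = 0.000393, upward, and adjusted p = 0.737 with an estimated correlation). Usp18, a deubiquitinase that damps interferon signalling, was 1.69-fold higher. Of 14 male-biased genes 6 fell and 8 did not pass (8 fell when adjusted over the list alone; camera adjusted p = 3.67e-06, downward, and adjusted p = 0.454 with an estimated correlation), and of 6 measured female-biased genes Sult1e1 and Cyp2b9 rose (3 rose when adjusted over the list alone; camera adjusted p = 0.00351, upward, and adjusted p = 0.27 with an estimated correlation). Among 17 hepatocyte markers, the cytochrome gene Cyp3a11 was 4.57-fold lower and the urea cycle gene Ass1 2.27-fold lower, 15 did not pass, and 3 fell when adjusted over the list alone. That list did not pass as a set (camera adjusted p = 0.15) but did without library 466 (0.00548), as did the myofibroblast list (camera adjusted p = 0.0741 with it and 0.0234 without it). Without that library both had adjusted p = 0.742 with an estimated correlation. The insulin receptor substrate gene Irs2 was 2.49-fold lower and the insulin-repressed gene Igfbp1 3.78-fold lower.

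Adding the clock score as a term, without library 466, ended the week 6 calls of Dbp, Per3, Npas2 and Arntl, which are part of the score, and of 6 other named genes. The log2 change without and with the term was -1.52 (SE 0.21) and -0.34 (SE 0.20) for Cry1, 0.88 (SE 0.15) and 0.33 (SE 0.17) for Ppara, and -2.64 (SE 0.37) and -1.16 (SE 0.45) for Elovl3, so the size itself shrank. For Usp18 it was 0.77 (SE 0.20) and 0.59 (SE 0.27), for Igfbp1 -1.91 (SE 0.43) and -1.17 (SE 0.62), and for G6pc -1.39 (SE 0.27) and -0.87 (SE 0.38). In these 3 the larger standard error had a part in the lost call, and the sizes overlapped within their errors. G6pc also did not pass without chow library 577 (log2 -1.15, adjusted p = 0.0559). Rgs16 and Loxl4 passed at smaller sizes (6.96 and 4.72, and -2.80 and -1.12). Trem2 (1.76 and 2.66), Gpnmb (3.47 and 4.25), Ccl2 (1.79 and 2.72) and Fgf21 (2.66 and 3.90) had larger ones. Diets did not overlap in the score.

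**Figure D2:**
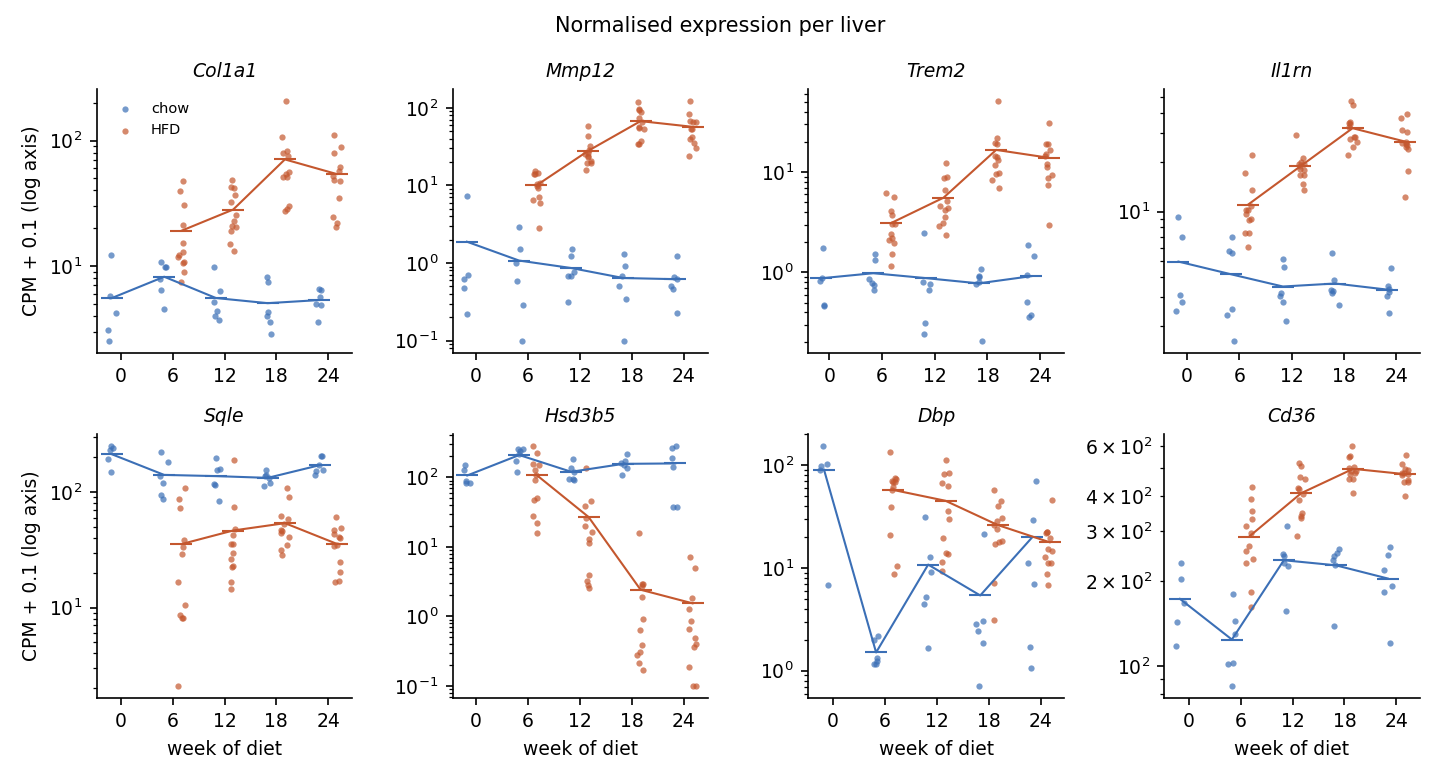
CPM plus 0.1 on a log axis against weeks on diet for Col1a1, Mmp12, Trem2, Il1rn, Sqle, Hsd3b5, Dbp and Cd36; points are the 77 libraries other than 466, and lines join the means of chow and HFD groups. Col1a1 stood at 70.7 ± 49.2 CPM on HFD at week 18 against 4.95 ± 2.20 on chow.

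At week 12, 14 of 18 cytokines and chemokines, 19 of 25 interferon response genes and 25 of 37 extracellular matrix genes were higher on HFD, and 23 of 24 cholesterol synthesis genes were lower. Col1a1 (chromosome 11, 94936224 to 94953042), the main fibrillar collagen chain, was 5.14-fold higher (log2 2.36, SE 0.46, adjusted p = 0.000111), at 28.1 ± 11.8 against 5.45 ± 2.31 CPM. Timp1, an inhibitor of matrix proteases, was 30.9-fold higher, from 0.059 ± 0.066 to 1.8 ± 1.21 CPM. Mmp12 (chromosome 9, 7344381 to 7369499) was 37.2-fold higher (log2 5.22, SE 0.50, adjusted p = 1.43e-12), above the chow mean in all 12 HFD livers. In total 2365 genes (17.6%) passed, 1352 higher and 1013 lower (449 and 128 by at least 2-fold). Without library 466, 3961 genes passed, all 2365 among them.

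Of the 37 extracellular matrix genes, 25 rose and 12 did not pass (29 rose when adjusted over the list alone; camera adjusted p = 1.79e-14, and adjusted p = 0.159 with an estimated correlation). Col3a1 was 3.43-fold higher (adjusted p = 6.32e-05) and Col16a1 2.04-fold (adjusted p = 1.86e-05). Of 25 matrix remodelling genes, 12 rose and 13 did not pass (15 rose and 2 fell when adjusted over the list alone; camera adjusted p = 2.58e-08, and adjusted p = 0.147 with an estimated correlation), and the plasminogen activator inhibitor gene Serpine1 was 8.44-fold higher. Of 13 stellate cell markers, Cygb, Pdgfrb and Hand2 rose and 10 did not pass (4 rose when adjusted over the list alone; camera adjusted p = 0.00536, and adjusted p = 0.325 with an estimated correlation). Cygb and the growth factor receptor gene Pdgfrb were 1.53-fold and 1.46-fold higher (adjusted p = 0.00479 and 0.00976). Of 11 myofibroblast contractile markers, Crip1, Tagln2, Vim, Tagln and Tpm1 rose, Cnn3 fell and 5 did not pass (6 rose and 1 fell when adjusted over the list alone; camera adjusted p = 0.00122, and adjusted p = 0.325 with an estimated correlation). Tpm1 and Vim were 1.64-fold and 2.11-fold higher. The smooth muscle actin gene Acta2 was 2.28-fold higher but did not pass (adjusted p = 0.175, and 0.0231 without library 466).

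Of 18 monocyte and macrophage markers, 14 rose and 4 did not pass (17 rose when adjusted over the list alone; camera adjusted p = 6.73e-11, and adjusted p = 0.147 with an estimated correlation). The endotoxin coreceptor gene Cd14 was 3.74-fold higher, the lysosomal gene Cd68 1.95-fold and the adaptor gene Tyrobp 1.9-fold. Of 14 lipid-associated macrophage markers, 9 rose and 5 did not pass (11 rose when adjusted over the list alone; camera adjusted p = 8.62e-10, and adjusted p = 0.0544 with an estimated correlation). Lgals3 was 3.75-fold higher and the glucan receptor gene Clec7a 3.53-fold. Gpnmb and Trem2 were 15.7-fold and 6.83-fold higher, and without chow library 576 their log2 changes moved from 3.97 to 5.91 and from 2.77 to 3.54. The osteopontin gene Spp1 was 1.82-fold higher and did not pass (adjusted p = 0.0997, and 0.0477 without library 466). All 7 MHC class II genes rose, also when adjusted over the list alone (camera adjusted p = 2.5e-05, and adjusted p = 0.248 with an estimated correlation), with H2-DMb1 2.53-fold, H2-Eb1 2.32-fold and H2-Aa 2.1-fold higher.

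Of 18 cytokines and chemokines, 14 rose and 4 did not pass (16 rose when adjusted over the list alone; camera adjusted p = 4.15e-13, and adjusted p = 0.0544 with an estimated correlation). Il1rn was 5.52-fold higher (log2 2.46, SE 0.26, adjusted p = 6.19e-11), the chemokine gene Ccl6 3.4-fold, Cxcl10 4.19-fold and Ccl2 4.19-fold. Of 25 interferon response genes, 19 rose and 6 did not pass (21 rose when adjusted over the list alone; camera adjusted p = 1.15e-16, and adjusted p = 0.0902 with an estimated correlation). Ifit3 was 2.49-fold higher, Usp18 2.44-fold and the guanylate binding protein gene Gbp3 2.86-fold, and Ifi27l2b, an interferon-inducible gene, was 7.18-fold higher. In the T and NK cell list only Ccl5 of 13 genes rose (3 rose when adjusted over the list alone; camera adjusted p = 0.0283, and adjusted p = 0.643 with an estimated correlation). Of 23 proliferation genes, Cdkn3 rose and 22 did not pass, and 0 passed when adjusted over the list alone (camera adjusted p = 0.00338, and adjusted p = 0.643 with an estimated correlation). Of 15 sinusoidal endothelial markers, Vwf, Pecam1, Lyve1 and Plvap rose (4 rose when adjusted over the list alone; camera adjusted p = 0.0182, and adjusted p = 0.566 with an estimated correlation), with Lyve1, a hyaluronan receptor gene, 2.03-fold and Plvap 1.58-fold higher.

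Of 24 cholesterol synthesis genes, 23 fell and 1 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 1.83e-21, and adjusted p = 0.0902 with an estimated correlation). The sterol reductase gene Tm7sf2 was 2.71-fold lower, the squalene synthase gene Fdft1 2.27-fold, Pmvk 2.59-fold and Sqle 2.97-fold. In the lipid droplet and lipid uptake list, 7 of 18 genes rose (8 rose and 1 fell when adjusted over the list alone; camera adjusted p = 0.00802, and adjusted p = 0.248 with an estimated correlation), with Cd36 1.73-fold and Plin3 1.47-fold higher. Of 14 male-biased genes 7 fell (8 when adjusted over the list alone; camera adjusted p = 2.16e-06, and adjusted p = 0.261 with an estimated correlation), and of 6 female-biased genes Sult1e1, Cyp2b13, Cyp2b9 and Cyp2a4 rose (5 when adjusted over the list alone; camera adjusted p = 0.00111, and adjusted p = 0.0902 with an estimated correlation). Cyp2b9 was 36.5-fold higher. Of 17 hepatocyte markers only Cyp3a11 fell, 4.49-fold, also when adjusted over the list alone (camera adjusted p = 0.0381, downward, and adjusted p = 0.802 with an estimated correlation).

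Rgs16 was 39-fold higher at week 12 (log2 5.29, SE 0.75, adjusted p = 4.06e-07), the metallothionein gene Mt2 7.62-fold higher and the stress response factor gene Atf3 3.87-fold higher. The retinoic acid hydroxylase gene Cyp26a1 was 6.72-fold lower and the pseudogene Serpina4-ps1 8-fold lower. Mup7, a major urinary protein gene, was 8.77-fold lower (log2 -3.13, SE 0.86), and -3.72 on the log2 scale without HFD library 486. Of the clock genes, Per1 and Dbp rose, Cry1, Npas2, Clock, Arntl and Nfil3 fell and 11 of 18 did not pass (6 rose and 5 fell when adjusted over the list alone), and the list did not pass as a set (camera adjusted p = 0.89); its median of 0.42 and its mean of 0.28 were positive while the test pointed downward. Clock itself was 1.45-fold lower, Cry1 2.05-fold and Npas2 3.37-fold, and with the clock score as a term Npas2 did not pass (log2 -0.40, SE 0.20, adjusted p = 0.125, against -1.75, SE 0.41, without the term and library 466). The bile acid and xenobiotic lists passed without library 466 (camera adjusted p = 0.0249 and 0.025, downward, and adjusted p = 0.46 and 0.422 with an estimated correlation), and with it they did not (camera adjusted p = 0.134 and 0.151).

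**Figure D3:**
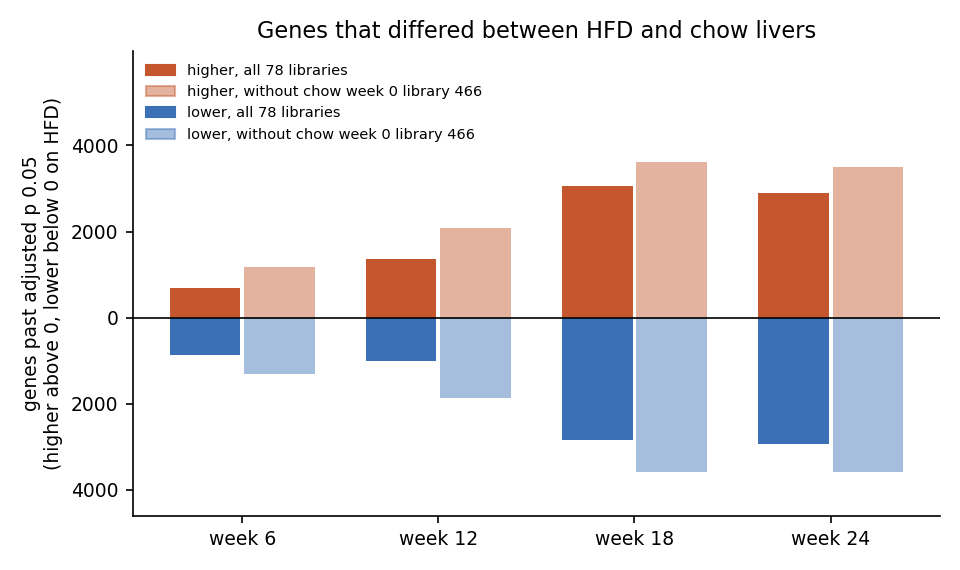
Number of genes past adjusted p = 0.05 between HFD and chow, higher on HFD above 0 and lower below 0, by week on diet; the paired bars are fits with and without library 466. With it, 3063 were higher and 2840 lower at week 18.

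At week 18 the liver on HFD differed from chow in 5903 genes, with 35 of 37 extracellular matrix genes, all 18 monocyte and macrophage markers and 17 of 18 cytokines and chemokines higher, and 12 of 14 male-biased genes lower. Col1a1 was 14-fold higher (log2 3.81, SE 0.48, adjusted p = 1.67e-09), at 70.7 ± 49.2 against 4.95 ± 2.20 CPM. Mmp12 was 115-fold higher (log2 6.84, SE 0.52, adjusted p = 3.58e-17) and Trem2 (chromosome 17, 48346401 to 48354147) 25.2-fold higher. Hsd3b5 (chromosome 3, 98618634 to 98630252), a male-biased steroid dehydrogenase gene, was 74.8-fold lower, at 2.32 ± 4.30 against 156.2 ± 36 CPM; its log2 change was -6.23, and -7.26 without HFD library 571. Of the 5903 genes, 3063 were higher and 2840 lower (1359 and 301 by at least 2-fold). Without library 466, 7199 genes passed, 5902 of the 5903 among them.

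Of the 37 extracellular matrix genes, 35 rose and 2 did not pass (36 rose when adjusted over the list alone; camera adjusted p = 6.57e-20, and adjusted p = 0.153 with an estimated correlation). The basement membrane gene Nid1 was 3.97-fold higher (log2 1.99, SE 0.21, adjusted p = 3.72e-12), Col16a1 3.03-fold, Col6a3 4.73-fold and Col3a1 7.03-fold. Of 25 matrix remodelling genes, 20 rose, Loxl4 and Mmp19 fell and 3 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 2.33e-09, and adjusted p = 0.153 with an estimated correlation). Timp1 was 14.8-fold higher, the urokinase receptor gene Plaur 6.06-fold and the lysyl oxidase gene Loxl2 3.06-fold. Of 13 stellate cell markers, 10 rose and 3 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.000267, and adjusted p = 0.191 with an estimated correlation). Pdgfrb was 2.63-fold, Cygb 2.55-fold and Pdgfra 2.25-fold higher. Of 11 myofibroblast markers, 7 rose, Cnn3 fell and 3 did not pass (8 rose and 1 fell when adjusted over the list alone; camera adjusted p = 0.00121, and adjusted p = 0.301 with an estimated correlation), with Tagln2 3.44-fold and Tpm1 2.54-fold higher. Acta2 was 2.45-fold higher without passing (adjusted p = 0.0608), and it passed without HFD library 571 (adjusted p = 0.0486), chow library 597 (0.0278) or library 466 (0.00265). Of 16 TGF-beta response genes, 11 rose, Inhba fell and 4 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.00134, and adjusted p = 0.191 with an estimated correlation). Tgfb1 was 1.99-fold higher, Tgfbi 2.07-fold and the receptor gene Tgfbr2 1.86-fold.

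Of 14 lipid-associated macrophage markers, 12 rose and 2 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 1e-11). That list passed at adjusted p = 0.0399 with an estimated correlation, and not without library 466 (adjusted p = 0.167 with an estimated correlation). Gpnmb was 54.4-fold higher (log2 5.77, SE 0.66, adjusted p = 1.09e-10), Clec7a 9.07-fold, Lgals3 6.54-fold and Spp1 7.33-fold. All 18 monocyte and macrophage markers rose, also when adjusted over the list alone (camera adjusted p = 1.47e-11, and adjusted p = 0.153 with an estimated correlation), with Cd68 3.17-fold, Tyrobp 2.87-fold and the Fc receptor chain gene Fcer1g 2.63-fold higher. Of 18 cytokines and chemokines, 17 rose, also when adjusted over the list alone (camera adjusted p = 8.55e-11, and adjusted p = 0.0773 with an estimated correlation). Il1rn was 9-fold, Ccl6 6.04-fold and Cxcl16 2.58-fold higher. Interferon response genes rose in 20 of 25 cases (21 when adjusted over the list alone; camera adjusted p = 2.18e-08, and adjusted p = 0.212 with an estimated correlation), and all 7 MHC class II genes rose, also when adjusted over the list alone (camera adjusted p = 3.48e-05, and adjusted p = 0.212 with an estimated correlation).

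In the resident Kupffer cell list Cd5l, Folr2, Kcna2 and Vsig4 rose, Cd163 fell and 3 of 8 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.0583, and 0.0327 without library 466, there adjusted p = 0.461 with an estimated correlation). The secreted scavenger protein gene Cd5l was 3.22-fold and the channel gene Kcna2 2.31-fold higher, while Clec4f, a Kupffer cell lectin gene, was 1.49-fold higher without passing (adjusted p = 0.106, and 0.00397 without library 466). Of 15 sinusoidal endothelial markers 5 rose (4 when adjusted over the list alone; camera adjusted p = 0.0795). Plvap was 1.96-fold and Lyve1 2.32-fold higher. The T and NK cell list did not pass (camera adjusted p = 0.0814; 3 of 13 rose, and 1 when adjusted over the list alone) but did without library 466 (0.02, and adjusted p = 0.461 with an estimated correlation).

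Of 23 proliferation genes, 18 rose (19 when adjusted over the list alone; camera adjusted p = 0.000762, and adjusted p = 0.581 with an estimated correlation). The proliferation marker gene Mki67 was 5.23-fold higher and the survivin gene Birc5 3.79-fold; Prc1, a spindle gene, was 4.79-fold higher, with a log2 change of 2.26 that moved to 1.68 without HFD library 568. Lcn2, which encodes an iron-sequestering acute phase protein, was 26.9-fold higher, and Orm2 was 5.97-fold higher. Saa1 was 7.83-fold higher, with a log2 change of 2.97 that moved to 2.29 without HFD library 532. The acute phase list did not pass as a set (camera adjusted p = 0.0795), with 9 of 20 genes higher and Hamp lower, also when adjusted over the list alone. Of 10 NRF2 targets, Nqo1, Hmox1, Abcc5, Slc7a11 and Srxn1 rose and Gclm and Gsta4 fell, also when adjusted over the list alone (camera adjusted p = 0.0257, and adjusted p = 0.191 with an estimated correlation), with Srxn1, a peroxiredoxin repair gene, 2.75-fold and the haem oxygenase gene Hmox1 2.06-fold higher. In the unfolded protein and stress response list, 5 genes rose and 10 fell of 21, also when adjusted over the list alone (camera adjusted p = 0.16): Atf3 and Gdf15 were 6.46-fold and 4-fold higher, and the chaperone gene Hyou1 was 2.39-fold lower.

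Hepatocyte transcripts were lower in several lists. Of 17 hepatocyte markers, 7 fell and 10 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.00892, and adjusted p = 0.586 with an estimated correlation). Without library 466 that list had camera adjusted p = 1.9e-08, and adjusted p = 0.167 with an estimated correlation. Cyp3a11 was 3.65-fold lower and the amino acid catabolism genes Tat and Hpd were 3.03-fold and 1.99-fold lower, while Alb was 1.38-fold lower without passing (adjusted p = 0.289, and 6.43e-05 without library 466). Of 14 male-biased genes, 12 fell (12 fell and 1 rose when adjusted over the list alone; camera adjusted p = 7.59e-08, and adjusted p = 0.191 with an estimated correlation). Elovl3 was 10.2-fold lower, and without library 466 its log2 change was -3.36, and -2.51 with the clock score as a term. Of 6 female-biased genes, 5 rose (5 rose and 1 fell when adjusted over the list alone; camera adjusted p = 0.0132, and adjusted p = 0.191 with an estimated correlation), and the estrogen sulfotransferase gene Sult1e1 was 38.2-fold higher, with a log2 change of 5.26 that moved to 5.96 without chow library 598. Mup7 was 33.3-fold lower (log2 -5.06, and -5.88 without HFD library 571). Of 22 bile acid genes, 11 fell and Abcc4 rose, also when adjusted over the list alone (camera adjusted p = 0.0181, and adjusted p = 0.586 with an estimated correlation). The transporter gene Slco1a1 was 10.6-fold lower and the hydroxylase genes Cyp7b1 and Cyp27a1 5.22-fold and 1.93-fold lower.

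Of 24 cholesterol synthesis genes, 20 fell (23 when adjusted over the list alone; camera adjusted p = 7.59e-09, and adjusted p = 0.301 with an estimated correlation), with Tm7sf2 3.37-fold, Cyp51 2.71-fold and Sqle 2.47-fold lower. Of 6 erythroid markers, Alas2, Hbb-bs, Hba-a1 and Hbb-bt fell (5 when adjusted over the list alone; camera adjusted p = 0.00949, and adjusted p = 0.301 with an estimated correlation), and Alas2, the first enzyme of haem synthesis in red cells, was 2.19-fold lower. Ly6d was 76.9-fold and Rgs16 24.8-fold higher, and without library 466 Rgs16 had a log2 change of 4.63, and 3.53 with the clock score as a term. The elastase gene Cela1, the single tested pancreas marker, was 6.96-fold lower, but chow library 597 held 391 CPM of it; without that library the log2 change moved from -2.80 to -0.98 (adjusted p = 0.00217). The glucose list passed without library 466 (camera adjusted p = 0.0287, downward, and adjusted p = 0.202 with an estimated correlation; 0.0583 with it).

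At week 24 the liver on HFD kept high levels of matrix, macrophage and chemokine transcripts, and every cholesterol synthesis gene was lower. Of 11 measured cholangiocyte markers 7 were higher, as were all 5 measured of the 12 neutrophil markers. Col1a1 was 10.3-fold higher (log2 3.37, SE 0.47, adjusted p = 2.19e-08), at 54 ± 28.1 against 5.25 ± 1.10 CPM. Mmp12 was 114-fold higher and Hsd3b5 121-fold lower (log2 -6.92, SE 0.74, adjusted p = 1.66e-11; -7.56 without HFD library 585). Fdft1 and Tm7sf2 were 3.35-fold and 4.24-fold lower (adjusted p = 5.64e-10 and 8.02e-10). In total 5819 genes (43.2%) passed, 2890 higher and 2929 lower (1325 and 312 by at least 2-fold). Without library 466, 7086 genes passed, 5817 of the 5819 among them.

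Of the 37 extracellular matrix genes, 33 rose and 4 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 1.62e-17, and adjusted p = 0.116 with an estimated correlation). Nid1 was 3.39-fold, Col16a1 2.77-fold, Col6a3 4.39-fold and Col3a1 6.04-fold higher. Of 25 matrix remodelling genes, 21 rose, Mmp19 fell and 3 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 4.65e-10, and adjusted p = 0.114 with an estimated correlation), with Timp1 22-fold and the urokinase gene Plau 4.96-fold higher. Of 13 stellate cell markers 9 rose (11 when adjusted over the list alone; camera adjusted p = 0.000196, and adjusted p = 0.189 with an estimated correlation), with Pdgfrb 2.49-fold and Cygb 2.29-fold higher. Of 16 TGF-beta response genes 12 rose (13 when adjusted over the list alone; camera adjusted p = 0.000151, and adjusted p = 0.114 with an estimated correlation), with Tgfbi 2.24-fold and Tgfbr1 1.57-fold higher. Of 11 myofibroblast markers, 7 rose, Cnn3 fell and 3 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.00466, and adjusted p = 0.357 with an estimated correlation). Tagln2 was 2.79-fold higher, and Acta2 was 1.82-fold higher without passing (adjusted p = 0.231); it passed from the libraries of the week alone (0.0246) and, without library 466, with flow cell (0.0369) or the clock score (0.0343) as a term.

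All 18 monocyte and macrophage markers rose, also when adjusted over the list alone (camera adjusted p = 4.74e-14, and adjusted p = 0.114 with an estimated correlation), with Ccr2 9.03-fold, Tyrobp 3.11-fold and Fcer1g 2.78-fold higher. Of 14 lipid-associated macrophage markers, 12 rose, Fabp5 fell and 1 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 1.5e-09, and adjusted p = 0.0814 with an estimated correlation). Gpnmb was 75.4-fold, Trem2 18.2-fold, Clec7a 7.39-fold, Lgals3 5.49-fold and Spp1 6.74-fold higher. Of 8 Kupffer cell markers, 5 rose and the haemoglobin scavenger receptor gene Cd163 fell 2.36-fold (6 rose and 1 fell when adjusted over the list alone; camera adjusted p = 0.0191, and adjusted p = 0.369 with an estimated correlation), and Cd5l was 3.35-fold higher. Of 18 cytokines and chemokines 17 rose, also when adjusted over the list alone (camera adjusted p = 1.4e-10, and adjusted p = 0.0814 with an estimated correlation): Il1rn 8.3-fold, Ccl6 5.3-fold, Ccl2 5.92-fold and Cxcl16 2.34-fold. All 7 MHC class II genes rose, also when adjusted over the list alone (camera adjusted p = 1.31e-05, and adjusted p = 0.189 with an estimated correlation), with H2-Eb1 3.57-fold and H2-Aa 3.34-fold higher.

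Of 25 interferon response genes 19 rose, also when adjusted over the list alone (camera adjusted p = 3.74e-09, and adjusted p = 0.189 with an estimated correlation), with the antiviral genes Oas2 3.34-fold, Mx1 3.8-fold and Xaf1 2.29-fold higher. Ubd, a ubiquitin-like protein gene induced by cytokines, was 17.1-fold higher. All 5 measured neutrophil markers rose, also when adjusted over the list alone (camera adjusted p = 0.0294, and adjusted p = 0.357 with an estimated correlation), though the list did not pass without library 466 (camera adjusted p = 0.0642). The growth factor receptor gene Csf3r was 2.26-fold higher. Nkg7, Gzmb, Gzma and Ccl5 rose of 13 T and NK cell markers, also when adjusted over the list alone (camera adjusted p = 0.138), with Ccl5 4.93-fold higher. Of 11 cholangiocyte markers 7 rose, also when adjusted over the list alone (camera adjusted p = 0.0262, and adjusted p = 0.357 with an estimated correlation), with Ehf 3.86-fold, Sox4 3.04-fold and Sox9 1.57-fold higher. Of 23 proliferation genes 10 rose (12 when adjusted over the list alone; camera adjusted p = 0.00672, and adjusted p = 0.679 with an estimated correlation), with Aurkb 4.67-fold and Prc1 3.64-fold higher. Of 15 sinusoidal endothelial markers 5 rose and Dnase1l3 fell, also when adjusted over the list alone (camera adjusted p = 0.161), with Lyve1 3.38-fold higher.

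All 24 cholesterol synthesis genes fell, also when adjusted over the list alone (camera adjusted p = 5.44e-17, and adjusted p = 0.131 with an estimated correlation), with Sqle 4.82-fold and Mvk 2.7-fold lower. Of 22 fatty acid and triglyceride synthesis genes, 10 fell, Scd2 rose and 11 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.0294, and adjusted p = 0.581 with an estimated correlation; camera adjusted p = 0.0844 without library 466). The acetate-activating gene Acss2 was 4.69-fold lower, the malic enzyme gene Me1 2.23-fold and the lipogenic regulator gene Thrsp 4.5-fold, and the desaturase gene Scd2 was 3.4-fold higher. The fatty acid synthase gene Fasn was 2.36-fold lower (log2 -1.24, adjusted p = 0.0112) but did not pass without chow library 563 (log2 -0.93, adjusted p = 0.0771). Of 18 lipid droplet and uptake genes 8 rose and Fitm1 fell, also when adjusted over the list alone (camera adjusted p = 0.0469, and adjusted p = 0.357 with an estimated correlation), with Cd36 2.34-fold, Plin3 1.45-fold, Plin2 1.23-fold and the droplet fusion gene Cidec 3.74-fold higher. PPAR-alpha targets went both ways, with 5 higher and 4 lower of 26 (4 higher and 4 lower when adjusted over the list alone; camera adjusted p = 0.842): Fgf21 was 6.25-fold and the uncoupling protein gene Ucp2 2.48-fold higher, and the carnitine transferase gene Cpt2 1.46-fold lower. That list's mean was 0.11 while its median of -0.07 and its test pointed downward.

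Of 17 hepatocyte markers 6 fell (5 when adjusted over the list alone; camera adjusted p = 0.0236, and adjusted p = 0.679 with an estimated correlation), among them Ass1 (2.21-fold), Cyp3a11 (2.24-fold) and the urea cycle gene Cps1 (2.1-fold). Alb was 1.25-fold lower without passing (adjusted p = 0.49, and 0.00701 without library 466). Of 14 male-biased genes 12 fell, also when adjusted over the list alone (camera adjusted p = 7.51e-08, and adjusted p = 0.189 with an estimated correlation). Mup7 was 88.8-fold lower, and its log2 change of -6.47 became -5.71 without chow library 546 and -7.53 without HFD library 585. Of 6 female-biased genes Sult1e1, Cyp2b13, Cyp2b9 and Cyp2a4 rose (5 when adjusted over the list alone; camera adjusted p = 0.0229, and adjusted p = 0.189 with an estimated correlation), with Sult1e1 9.23-fold higher. Of 22 bile acid genes 8 fell and Abcc4 rose, also when adjusted over the list alone (camera adjusted p = 0.0294, and adjusted p = 0.679 with an estimated correlation), with Cyp7b1 5.17-fold, Cyp27a1 2.13-fold and Slco1a1 13.4-fold lower; with flow cell as a term the log2 change of Slco1a1 was -4.80 in place of -3.74. All 6 measured erythroid markers fell, also when adjusted over the list alone (camera adjusted p = 0.00153, and adjusted p = 0.189 with an estimated correlation), with Alas2 2.09-fold and Hba-a2 2.07-fold lower.

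Of 10 NRF2 targets 5 rose and Gsta4 fell (6 rose and 1 fell when adjusted over the list alone; camera adjusted p = 0.0444, and adjusted p = 0.192 with an estimated correlation), with Hmox1 2.39-fold higher. The acute phase list had 8 of 20 genes higher, also when adjusted over the list alone (camera adjusted p = 0.0841), with Lcn2 26.3-fold and Saa1 5.62-fold higher. The xenobiotic list had 4 of 19 genes higher and 8 lower, also when adjusted over the list alone (camera adjusted p = 0.186, and 0.0495 without library 466, there adjusted p = 0.39 with an estimated correlation). In the glucose and insulin list Ppargc1a rose and Igf1, Irs2, Igfbp2 and G6pc fell of 13 (1 rose and 3 fell when adjusted over the list alone; camera adjusted p = 0.186), with the binding protein gene Igfbp2 3.92-fold lower. The stress response list had 4 of 21 genes higher and 4 lower, also when adjusted over the list alone (camera adjusted p = 0.841), with a median of -0.01 against a mean of 0.14 and an upward test. Of the 18 clock genes, Cry1, Clock and Rorc fell and 15 did not pass (2 fell when adjusted over the list alone; camera adjusted p = 0.503).

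Of 7 adipocyte markers Car3 fell at week 24, also when adjusted over the list alone (camera adjusted p = 0.529), and of 3 mesothelial markers Wt1 rose 3.75-fold, also when adjusted over the list alone (camera adjusted p = 0.511). Of 9 B and plasma cell markers 0 passed, also when adjusted over the list alone (camera adjusted p = 0.99). Cela1 fell at week 24 as the single tested pancreas marker, and no skeletal muscle marker was expressed highly enough to be tested.

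**Figure D4:**
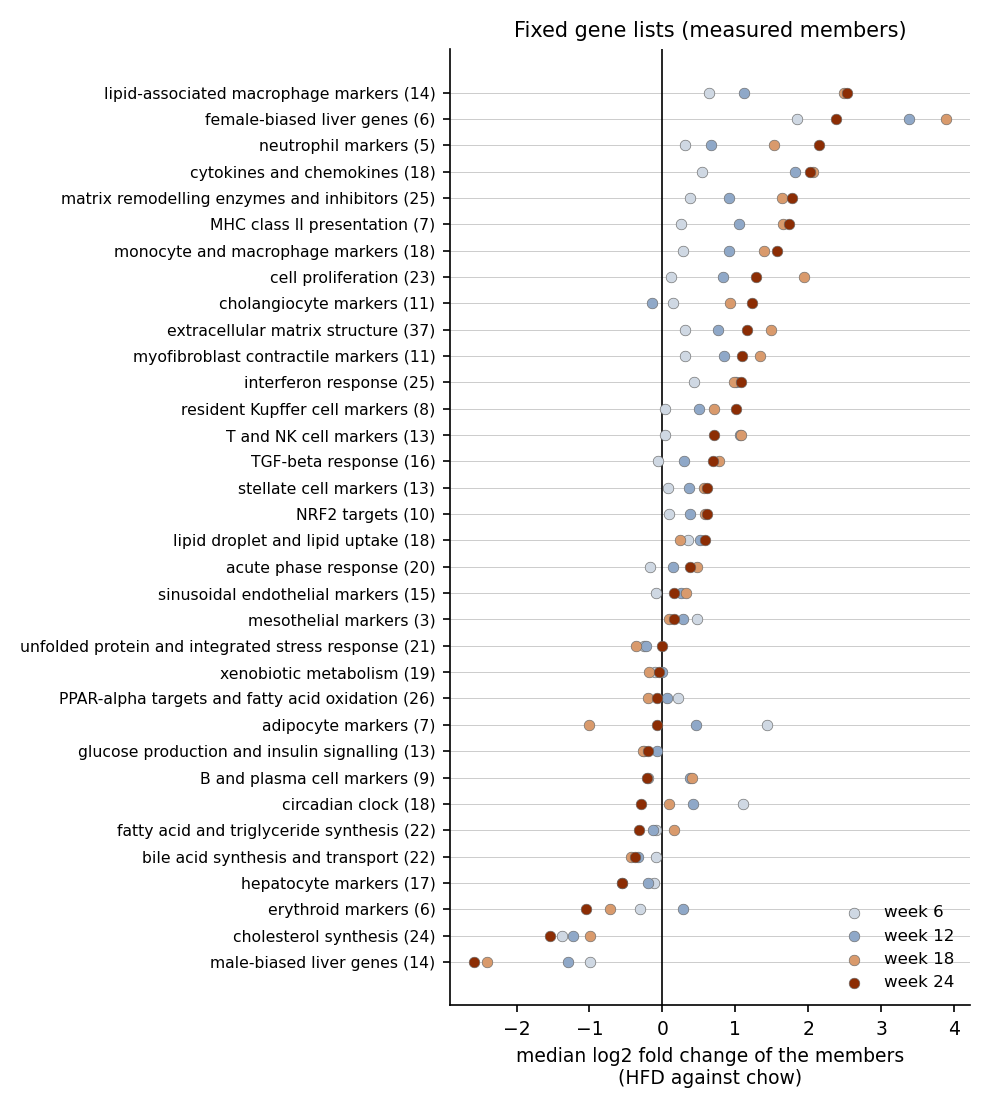
Median log2 fold change, HFD over chow, of the measured members of each fixed list (vertical axis) at weeks 6, 12, 18 and 24; members with an empty group stand at their bound. The matrix list moved from 0.32 at week 6 to 1.49 at week 18, and the cholesterol synthesis list stood at -1.37 at week 6 and -1.54 at week 24.

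The number of lists past the camera test was 12 of 34 at week 6, 17 at week 12, 18 at week 18 and 23 at week 24. With an estimated correlation it was 1 (cholesterol synthesis), 0, 1 (lipid-associated macrophage markers) and 0. From the libraries of the week alone, the matrix remodelling, monocyte and macrophage, and cytokine lists did not pass at week 6 (camera adjusted p = 0.105, 0.105 and 0.0501), nor the NRF2 list at week 18 (0.0622) or the fatty acid synthesis and NRF2 lists at week 24 (0.107 and 0.0541). In these fits 2 to 5 other lists per week did pass. With flow cell as a term the lipid droplet list did not pass at week 24 (0.0739). Median, mean and test also differed in sign for the TGF-beta, acute phase, neutrophil, T and NK cell and xenobiotic lists at week 6, the xenobiotic list at week 12, and the xenobiotic, clock and fatty acid synthesis lists at week 18, and the sets did not pass there. Across weeks, which share no library, 621 genes passed at all 4 weeks in 1 direction, 261 higher and 360 lower. Of the 1352 genes higher at week 12, 1227 were also higher at week 18, against 307.7 for independent lists.

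As an interaction, a change of the diet effect with time passed in 1770 genes. From week 6 to 24 the change passed in 2069, 1188 towards a larger log2 fold change and 881 a smaller one. Without library 466 these counts were 3931 and 3856, all 1770 and 2069 among them. With the clock score as a term too, the interaction had 2163 (1243 of the 1770). Col1a1 rose by a further 4.43-fold from week 6 to week 24 (log2 2.15, SE 0.62, adjusted p = 0.0135), Col3a1 by 2.86-fold and Cd68 by 2.19-fold (adjusted p = 0.00275). Spp1 gained 3.44-fold and Trem2 5.37-fold, the latter with adjusted p = 0.0249, and 0.0584 with no filter on low counts. Tgfb1 and Col1a2 gained 1.74-fold and 2.44-fold without passing (adjusted p = 0.0534 and 0.058), and passed without library 466 (0.0158 and 0.0273). Gpnmb did not pass (adjusted p = 0.336) in edgeR and did in DESeq2 (adjusted p = 0.047). In the matrix list 23 of 37 genes had a larger effect at week 24 and 0 a smaller one; in the monocyte and macrophage list it was 14 of 18, and in the MHC class II list 7 of 7.

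For several acute phase and stress genes the ratio of HFD to chow was larger at week 24 while the chow level was lower there. The ratio grew 15.6-fold for Saa1 and 30.6-fold for Saa2 (log2 3.96 and 4.94; 3.35 and 4.14 with flow cell as a term), 8.51-fold for Lcn2 and 7.48-fold for Mt2. On chow Saa1 stood at 857.3 ± 1460 CPM at week 6, with 3647 in the highest library, and at 40.4 ± 6.54 at week 24, and on HFD at 309 ± 367 and 227.1 ± 54.8. Lcn2 stood at 41.3 ± 70.4 and 5.08 ± 1.62 CPM on chow and at 127.4 ± 238 and 132.6 ± 38.9 on HFD. In the acute phase list 3 of 20 genes had a larger effect at week 24. Egr1 had a change of 4.25 (adjusted p = 0.000409), with its week 6 value resting on chow library 577 as described. The log2 fold change moved downward by -5.96 for Hsd3b5 (SE 1.02, adjusted p = 0.000132) and by -4.51 for Mup7 (-5.32 with flow cell as a term), both of which were further below chow at week 24 than at week 6. It moved by -5.58 for Dbp, which did not pass at week 24 (log2 -0.21, adjusted p = 0.798), and by -4.09 for Rgs16, whose rise was larger at week 6. Some effects did not differ detectably between weeks 6 and 24: the change was 0.02 for Cd36 (SE 0.26), -0.28 for Sqle (SE 0.61), -0.01 for Fgf21 (SE 0.63) and -0.11 for Ldlr (SE 0.28), with adjusted p = 0.978, 0.793, 0.994 and 0.825.

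Between neighbouring weeks few genes passed. From week 6 to week 12 the effect changed in 7 genes, 5 larger and 2 smaller (1281 at unadjusted p below 0.05), and in 26 without library 466. Jun, an immediate early transcription factor gene, gained 3.11-fold (adjusted p = 0.0286) and the phosphodiesterase gene Pde7b 1.97-fold, while Akap8 and Rexo4 changed by -0.49 and -0.43 on the log2 scale. With no filter on low counts these 4 had adjusted p = 0.0913. From week 12 to week 18 it changed in 7 genes, 6 larger and 1 smaller (1384 at unadjusted p below 0.05), and in 107 without library 466. Mapt, the tau gene, gained 2.66-fold, the annexin gene Anxa5 1.98-fold (adjusted p = 0.0105), the kinesin gene Kifc3 1.98-fold and the lysosomal phospholipase gene Pla2g15 1.64-fold; Cela1 had a log2 change of -2.88, with chow library 597 at week 18 holding 391 CPM of it. Spp1 gained 4.02-fold without passing (adjusted p = 0.124, and 0.0322 without library 466). From week 18 to week 24 only Arl4a passed, a gain of 1.91-fold (adjusted p = 0.0132; 916 genes at unadjusted p below 0.05, and 3 genes past in DESeq2). The step in Col1a1 was 1.14, 1.45 and -0.44 on the log2 scale over the 3 intervals (adjusted p = 0.561, 0.39 and 1), and that in Trem2 1.01, 1.89 and -0.47 (adjusted p = 0.706, 0.351 and 1).

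The chow groups differed between weeks, with age and time of sampling not separated, as the clock score was 3.07 ± 1.90 in 5 libraries at week 0 and between -1.93 and 0.01 later. Between week 0 and week 24 on chow 2658 genes passed, 708 higher and 1950 lower at week 24, but the week 0 group holds library 466. Without it 476 genes passed, 221 higher and 255 lower, and 323 were among the 2658. Serpina4-ps1 was 10.3-fold higher at week 24 (log2 3.36, SE 0.66, adjusted p = 0.000149), the mitochondrial carrier gene Slc25a30 4.4-fold higher, the retinoic acid hydroxylase gene Cyp26b1 2.89-fold higher and Plin2 1.41-fold higher, and Mt2 was 7.84-fold lower. From only the 12 libraries compared, 0 genes passed in edgeR (1077 at unadjusted p below 0.05, and 19 past in DESeq2), and these 5 had similar sizes (log2 3.35, 2.13, 1.51, 0.48 and -2.98) with adjusted p = 0.543. Several large values rested on library 466: Fabp4 had a log2 change of -5.15 with it and -0.18 without it, Scd2 -3.14 and -0.46, Mki67 -4.38 and 0.11, Ikzf1 -3.13 and 0.07, Themis -3.08 and 0.62, Acta2 -2.80 and 0.75, and Cidec -2.12 and 1.42. Cyp2b9 and Elovl3 were 4.78-fold and 2.85-fold higher with it, and did not pass without it (log2 1.95 and 1.32, adjusted p = 0.198 and 0.114). The difference was 0.10 for Ldlr (SE 0.22, adjusted p = 0.807) and -0.01 for Alb (SE 0.41, adjusted p = 0.994), and without library 466 it was -0.16 and -0.27 (adjusted p = 0.58 and 0.233). Over all 5 chow groups 2686 genes passed, and 1278 without library 466, of which 808 were shared.

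Several named genes belong to families with near-identical copies, and reads that fit more than 1 copy were not assigned to a gene. Values of Cyp2b9, Cyp3a11, Mup7, Orm2, Saa1, Saa2 and Hba-a2 are therefore uncertain for the single gene. Alignments that were not unique made up 37.6% of the HTSeq tally on chow and 33.6% on HFD.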

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

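The tests of the 3 patterns weighed here, the splits and list counts at weeks 6 and 12, and the chow splits without library 466, were chosen after their results were seen; the other tests were planned. For 294 groups of 6 values, Dixon's test compared the gap between the most extreme library and its neighbour with the group's range. The ratio was past the critical value in 25, many of them in library 466. Elsewhere flags were near the 5 percent that chance gives. For library measures, the ratio was 0.625 for gene counts and 0.71 for genes with a read in week 18 chow library 596, and 0.906 for genes with a read and 0.722 for the mitochondrial percent in week 0 chow library 466. Library 466 also stood apart in log2 CPM of Alb (0.969), Ldlr (0.927), Scd2 (0.926), Fabp4 (0.912), Ikzf1 (0.847), Serpina4-ps1 (0.815), Mki67 (0.787), Acta2 (0.768), Cidec (0.662) and Themis (0.632). At week 6 the chow libraries flagged were 577 in Egr1 (0.639), 477 in Cyp26a1 (0.631) and 574 in Usp18 (0.631). At week 12 they were 576 in Mup7 (0.644) and 475 in Acta2 (0.634). At week 18 they were 597 in Cela1 (0.905) and Cyp27a1 (0.751), 524 in Trem2 (0.767), 599 in Cd5l (0.648) and 598 in Tgfbi (0.628), and at week 24 library 562 in Mvk (0.64).

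The diet effect differed between weeks in 1770 genes by the interaction and between weeks 6 and 24 in 2069. Of 139 named genes, 66 passed in that change, given as log2, week 24 less week 6. For matrix, stellate cell and contractile genes it was Col1a1 2.15, Col3a1 1.52, Col16a1 0.85, Col6a3 1.43, Nid1 1.42, Mmp12 3.57, Loxl2 0.88, Loxl4 2.59, Serpine1 2.36, Plau 1.62, Pdgfrb 1.31, Pdgfra 1.08, Cygb 0.98, Vim 1.21, Tpm1 1.02, Tagln2 1.08, Tgfbi 0.78 and Tgfbr1 0.50. For macrophage, endothelial, antigen presentation and chemokine genes it was Lgals3 1.41, Trem2 2.42, Clec7a 1.94, Spp1 1.78, Cd14 2.05, Cd68 1.13, Tyrobp 1.25, Fcer1g 1.20, Ccr2 1.76, Cd5l 1.34, Kcna2 1.32, H2-DMb1 1.51, H2-Eb1 1.60, H2-Aa 1.40, Il1rn 1.64, Ccl6 1.68, Cxcl16 0.85, Ccl5 1.99 and Lyve1 1.47. For clock genes it was Dbp -5.58, Per3 -3.10, Npas2 2.47, Cry1 0.96 and Arntl 1.67. For stress, acute phase, immediate early and interferon genes it was Lcn2 3.09, Saa1 3.96, Saa2 4.94, Mt2 2.90, Hmox1 1.27, Atf3 1.63, Egr1 4.25, Oas2 1.14 and Ifi27l2b 1.78. For the remaining genes it was Rgs16 -4.09, Cyp2b9 -3.29, Cfd -3.61, Csad 0.94, Igfbp1 2.33, Mup7 -4.51, Serpina4-ps1 -4.04, Slco1a1 -3.42, Hsd3b5 -5.96, Cela1 -1.54, Sox9 1.36, Thrsp -2.07, Cpt2 -0.40, Ucp2 1.10 and Igfbp2 -1.37.

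Markers outside the tested genes stood out in 2 libraries. The 8 skeletal muscle markers summed to 983.3 CPM in week 0 chow library 466. The 12 pancreas markers summed to 3012 CPM in week 18 chow library 597, against 47.8 in the next library apart from 466, with Ctrb1 at 671.8, Pnlip at 473.2 and Cpa1 at 340.8 CPM.

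Library 466 lacked hepatocyte transcripts, with a median hepatocyte marker at 0.052% of its mean in the other 5 week 0 libraries. That is far below what a liver sample mixed with another tissue would leave, and 0 of the other 77 libraries had Alb below 10% of the median library, so no partner for an exchange of labels within the series was found. All 8 skeletal muscle markers were above the highest of the other 77 libraries, beside the thymus, brown fat and airway transcripts reported. A candidate explanation is that a sample of another tissue, or of several, carries this label. No biological explanation was tested.

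Clock genes differed between the diets, most at week 6, where the clock score differed by 4.04 and at week 24 by 0.57 (exact permutation p = 5.39e-05 and 0.31). Flow cell as a term left 15 of the 16 clock genes called at week 6 called in the same direction, which argues against it as the cause. All 10 score genes differed at week 6 in the sense of their phase group, as a shift in time of day or feeding at sampling could give. In no week can these be told apart from a diet effect, as the labels give no sampling time. With the score as a term, 798 of the 2489 genes called at week 6 without library 466 were called in the same direction (1170 in all). The median size was 0.794 times and the median standard error 1.31 times that without the term. Week 6 scores did not overlap (chow up to -1.49, HFD from 0.5), so the term cannot tell clock from diet there or in changes from week 6. Size and error were not separated.

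Matrix and macrophage transcripts were higher on HFD at week 18. A lower share of hepatocytes would raise the markers of every other cell type alike, but the macrophage score rose more than the sinusoidal endothelial score, by 1.10 (SE 0.15, exact permutation p = 5.39e-05), above the highest chow library in 12 of 12 HFD livers. The endothelial score itself rose by 0.32 (SE 0.03) and the hepatocyte score fell by 0.72 (SE 0.06), so a lower share stays open for part of the change. With flow cell as a term 34 of the 35 matrix genes called higher stayed so. More macrophages and matrix-producing cells, or more transcript in each, may both contribute as a hypothesis, and the files hold no cell counts that would separate them.

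Other splits of the same libraries into groups of the same sizes were drawn 100 times per result, the real split included. Chance can be excluded for the genes at week 6 (1 split as large; 1557 genes, highest other 555), week 12 (1; 2365 and 1504), week 18 (1; 5903 and 1993) and week 24 (1; 5819 and 4298). Splits mix the diets and lose the diet effect, so they cannot test its interaction with week (1; 1770 and 8). Nor can they test its changes from week 6 to 24 (1; 2069 and 22) or 6 to 12 (1; 7 and 2). The same holds for weeks 12 to 18 (2; 7 and 49) and 18 to 24 (4; 1 and 1). Without library 466 chance can be excluded for the chow pair (1; 476 and 387) and chow over weeks (1; 1278 and 330). With that library in every split these were 3 (2658 and 2936) and 1 (2686 and 2224). The other splits gave a median of 1769 and 1536 genes, against 0 and 11 without it. So library 466 is a structure of its own, and these counts cannot exclude chance. Fewer than 5 splits were as large for the lists at week 24 (4; 23 and 25), and no share is adjusted over the 17 counts. Chance is at most weakly excluded there. It cannot be excluded for the lists at week 6 (34; 12 and 21), week 12 (11; 17 and 21) or week 18 (21; 18 and 22).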

How the results depend on the processing

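The fits without chow library 466, with the clock score and with flow cell without that library were chosen after the data were seen; the others were planned. For counts of genes and lists, 145 values stayed within 1.5 times the one reported and 24 did not. With DESeq2 size factors and with a filter of 1 CPM in 6 libraries, all 299 gene results kept their direction and side of the threshold, and with flow cell as a term 295 of 299 did. Leaving out 1 library of a week gave 1243 to 1574 genes at week 6, 1753 to 2413 at week 12, 5338 to 5966 at week 18 and 5282 to 5856 at week 24. With no filter on low counts the interaction had 1117 genes, the change from week 6 to 24 had 1340, that from week 6 to 12 had 1 and that from week 18 to 24 had 2. In DESeq2 the change from week 6 to 12 had 25 genes, that from week 12 to 18 had 25 and that from week 18 to 24 had 3. Week 12 gave 3910 genes from its own libraries alone, and in such fits Ldlr at weeks 6, 12 and 18, Acta2 and Spp1 at week 12, Acta2, Alb and Clec4f at week 18 and Acta2 and Alb at week 24 also passed. From only the 12 chow libraries compared, edgeR gave 0 genes between weeks 24 and 0 (1077 of 11953 at unadjusted p below 0.05, and 19 in DESeq2), and from only the 30 chow libraries the change over weeks had 522. Without library 466 there were 2489 genes at week 6, 3961 at week 12, 3931 in the interaction, 3856, 26 and 107 in the changes from week 6 to 24, 6 to 12 and 12 to 18, 476 between chow weeks and 1278 over the chow weeks. The clock score term gave 4092 genes at week 12 and the flow cell term 3982, both without library 466. With an estimated correlation 1, 0, 1 and 0 lists passed at weeks 6, 12, 18 and 24 (3, 8, 8 and 8 at unadjusted p below 0.05). Without library 466 the chow difference turned to 0.069 for Ikzf1, 0.62 for Themis, 0.11 for Mki67, 0.75 for Acta2 and 1.42 for Cidec, none past the threshold, since that library held their high week 0 values. With the clock score as a term and without library 466 the week 6 difference turned to -0.51 for Per3 and 0.20 for Arntl, both part of the score. Apart from these the cause of each move was not tested.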

Other observations

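The relations below were set out before their values were seen, on scores that are means of log2 CPM over a fixed list, less the mean of the week, over 48 HFD libraries. The matrix score differed between livers of the same diet and week, and 5 relations with it were tested by permutation, two-sided, with p adjusted over the 5. The matrix score was higher where the lipid-associated macrophage score was higher (Pearson r = 0.843, Spearman rho = 0.781, adjusted permutation p = 2.5e-05 for both; the unadjusted 1e-05 is the smallest that 100000 permutations can give). Without libraries 568 and 585, the farthest from the median, r was 0.801, with flow cell taken out it was 0.83, and within weeks 6, 12, 18 and 24 it was 0.88, 0.792, 0.887 and 0.776. It was also higher where the proliferation score was higher (r = 0.787, rho = 0.794, adjusted permutation p = 2.5e-05 for both; 0.75 without libraries 568 and 499, 0.775 with flow cell taken out, and 0.867, 0.511, 0.892 and 0.699 within weeks). These values are consistent with a shared process in livers of 1 week, as a hypothesis; cell numbers were not measured.

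The matrix score was higher where the male-biased score was lower (r = -0.414, rho = -0.445, adjusted permutation p = 0.00737 and 0.0042). Without libraries 571 and 486, r was -0.41, with flow cell taken out -0.372, and within weeks -0.507, 0.045, -0.611 and -0.563, so the relation was not seen within week 12. With the lipid droplet score r was 0.08 (95% interval -0.223 to 0.368, rho = 0.186, adjusted permutation p = 0.592 and 0.216), and a weak relation in either direction cannot be told apart from none; it was 0.007 without libraries 548 and 518, 0.169 with flow cell taken out, and 0.182, 0.35, -0.409 and 0.072 within weeks. With the clock score r was -0.321 (adjusted permutation p = 0.0364) and rho -0.271 (adjusted permutation p = 0.0891). That relation rests in part on libraries 549 and 568, without which r was -0.201; it was -0.236 with flow cell taken out and -0.368, -0.148, -0.366 and -0.619 within weeks.

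Chow library 495 of week 24 held 0.11 CPM of each of the Y-linked genes Ddx3y and Eif2s3y and 0 of Kdm5d and Uty, against at least 68.8, 47.8, 20.6 and 17.2 CPM in the other 76 libraries apart from 466, and it held 0 CPM of Xist. Chow library 577 of week 6 held 288.1 CPM of Fos (next highest 12.8), 806.8 of Egr1 (next 118.8 in library 466, then 97.1) and 19.9 of Il1b (next 13.1).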
